A study of Mus musculus with 8 samples.

How the data were processed

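Hepatocyte DNA (test, Cy5, red) and wild type splenocyte DNA of the other sex (reference, Cy3, green) were digested with AluI and RsaI, labelled and hybridised to Agilent oligonucleotide arrays, per the labels' protocols. There was 1 hybridisation per sample and no dye swap. A positive log2 ratio means more hepatocyte than reference DNA. The deposited spot signals are intensity values, both the raw median signals and the processed signals, which the authors' software had background-subtracted and dye-normalised by a linear method, per the file headers. The deposited log ratio is the log10 of the red over the green processed signal, per the file headers, and the value table of the series held the same numbers (0 values differed), so its scale, direction and lack of further centring are those of the scanner files. The file headers name Agilent Feature Extraction 10.10.0.23 and build mm9, whereas the submitters' processing notes name Feature Extraction 9.5.

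Log10 ratios were multiplied by the log2 of 10, spots of 1 probe were averaged and each array was centred on the median of its autosomal probes, with no loess or quantile step. Control spots, non-uniform spots, spots saturated in both channels and spots well above background in neither channel were left out, which removed 47 to 156 of 174305 spots per array. Before centring, the autosomal medians lay between 0.0078 and 0.096 (log2). The lowest share of spots well above background in any channel of any array was 99.9%. Between arrays, Pearson correlations across autosomal probes without chromosome 16 ran from 0.804 to 0.949, and probes are not independent replicates. The lowest correlation over all probes was 0.285, between arrays of opposite sex. For arrays, precision is limited by their number.

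Each chromosome was summarised by the median of its probes, with a jackknife over 5-Mb blocks, and called at an absolute median of 0.1. Segments came from penalised least squares with a penalty of 40 noise variances per breakpoint, at least 10 probes, single probes pulled to within 3 noise SDs of the median of 7 neighbours, and a call at an absolute mean of 0.2. The chromosome 16 regions were found in the same way on the mean Hgd+/- Fah-/- profile minus the mean of the other 4 arrays, after the data had been seen. The share of copies missing was computed as 1 minus 2 to the power of the difference divided by 0.94, the log2 response to the 2-fold X difference. It is relative to the autosomal median and assumes that response on every chromosome. Bins of 1 Mb with at least 10 probes were tested on the mean of their probes with limma (lmFit and eBayes) and Benjamini-Hochberg adjustment at 0.05. The 3 group contrasts shared 1 fit of all 8 arrays, and bins of 1 chromosome are not independent. Values of 1 number per array were compared by two-sided exact permutation tests over all arrangements of the arrays.

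Groups, replicate numbers and sexes came from the labels. The array positions in the files showed 2 slides of 4 arrays, with wild type and Hgd-/- Fah-/- on slide 1 and all Hgd+/- Fah-/- samples on slide 2. The tests, the alternatives, the gene lists and the naming rule were fixed before the data were examined, unless the text says otherwise. The rule named the members of the fixed lists, up to 10 genes per direction and contrast, and the position, probes and mean of about 10 called segments. The fixed lists were tyrosine breakdown, chromosome 16 landmarks, liver growth and tumour genes, loci known to differ in copy between strains, antigen receptor loci, and X and Y landmarks. The probes carry mm9 positions and no gene names, and the gene table used here is of GRCm38.p6. It served only for names, chromosomes and gene order, no coordinate was converted, and 21 of the 22 strain loci and all genes of the other lists of named genes were matched. The region around Hgd, the 3 gene-level contrasts and the correction for GC content were therefore not run, so no gene was named by its own ratio. Some members of the fixed lists are not reported here. Single segments and bins outside the rule were named after their values were seen.

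Alternatives were other centring, no spot filter, normexp background correction with an offset of 50, the value table of the series, means or medians of probes, other thresholds, penalties, probe minimums and bin sizes, the sex or the replicate number as a block, limma-trend with robust variances, and each array left out. Normexp was planned on mean signals, and median signals were used because the files used here hold those. The slide as a block could not be fitted for contrasts with the Hgd+/- Fah-/- group. The methods were tested on simulated data. For segments of 1 array on 6274 probes, a planted log2 shift of -0.3 was recovered in 95.0% of 20 trials at 300 probes and in 100% at 2000 probes, but in 0% at 30 probes. A shift of -0.2, equal to the call threshold, was recovered in 40.0% at 300 and 55.0% at 2000 probes. In 2287 simulated bins for the Hgd+/- Fah-/- samples against the others, planted shifts of -0.4, -0.2, -0.1 and 0.1 were recovered in 100%, 96.0%, 92.0% and 98% of 50 bins each, with 10 false calls among 2087 unchanged bins. The simulated spread was that within the 3 groups, and no difference between wild type and Hgd-/- Fah-/- was planted. In the data such differences add to the spread of the other 4 arrays, so the shares may be too high. The simulated noise was independent between bins, with its spread taken from bins outside chromosome 16, so these shares do not carry over to that chromosome. In the data its first region differed by -0.12, yet 20 of its bins did not pass, all between 3000001 and 25000000. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.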

Results

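Genomic DNA of mouse hepatocytes was profiled on 8 array CGH hybridisations, which compare the copy number of a test DNA with that of a reference DNA along the genome. Wild type hepatocytes were measured on 2 arrays, hepatocytes without Hgd and Fah (Hgd-/- Fah-/-) on 2 arrays and hepatocytes from repopulated livers with 1 functional Hgd copy and no Fah (Hgd+/- Fah-/-) on 4 arrays, the last 2 groups after withdrawal of NTBC. Fah encodes fumarylacetoacetate hydrolase, the last enzyme of tyrosine breakdown, and its loss lets toxic intermediates build up. Hgd encodes homogentisate dioxygenase, which acts upstream, so that cells without Hgd form none of these intermediates. NTBC (nitisinone) blocks the pathway further upstream, at Hpd, and protects Fah-deficient liver. The arrays asked whether hepatocytes that repopulate a Hgd+/- Fah-/- liver under this selection carry chromosome losses or gains. Each array held 174305 probe spots for 170305 distinct probes, of which 161460 were autosomal, with a median spacing of 10843 bp. Between 47 and 156 spots per array were left out, and the noise of a single probe lay between 0.28 and 0.43 on the log2 scale. The number of arrays limits the precision of each group. The labels call the samples biological replicates without saying that each came from its own animal, so p-values measure the spread between these samples.

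Hepatocyte DNA was paired with wild type splenocyte DNA of the other sex, so the sex chromosomes carried a known copy difference on every array. The median log2 ratio of the 8723 X probes was 0.94 ± 0.013 (SD, n = 5) for female hepatocytes and -0.93 ± 0.0024 (SD, n = 3) for male hepatocytes. The difference of 1.87 gave a two-sided exact permutation p of 0.0357, the smallest that 5 against 3 arrays allow. The 122 Y probes had medians between -4.35 and -3.87 in the 5 female samples and between 3.78 and 4.62 in the 3 male samples. Every sample thus matched the sex in its label, and a 2-fold copy difference moved the log2 ratio by 0.94 on average. Male-specific genes such as Sry, Uty and Ddx3y and X-linked genes such as Xist, Otc and Hprt belong to the fixed lists of 8 distinct Y and 8 distinct X landmarks, all of which lie on these chromosomes in the GRCm38.p6 gene table.

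Chromosome 16, which carries Hgd, was lower in all 4 Hgd+/- Fah-/- samples and was called in no other sample. Its median log2 ratio over 6274 probes was -0.34, -0.25, -0.28 and -0.40 in replicates 1 to 4, with standard errors of 0.028, 0.025, 0.037 and 0.023 from a jackknife over 5-Mb blocks within each array. The mean was -0.32 ± 0.069 (SD, n = 4), against -0.0034 ± 0.0037 (SD, n = 4) in the other arrays, where wild type gave -0.0015 and -0.0057 and Hgd-/- Fah-/- gave -0.0072 and 0.00090. The difference of -0.31 had a two-sided exact permutation p of 0.0286, the smallest of the 70 arrangements of 4 against 4 arrays. Scaled by the response of the X chromosome, 20.7% ± 4.01 (SD, n = 4) of the chromosome 16 copies were missing on average from the sampled DNA, with a range of 16.7% to 25.7% over the 4 samples. The difference was -0.26 among female samples (exact p = 0.20) and -0.37 among male samples (exact p = 0.667), group sizes that cannot reach 0.05. The 4 Hgd+/- Fah-/- arrays shared a slide that held no other group, so slide and group cannot be told apart for this comparison.

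**Figure D1:**
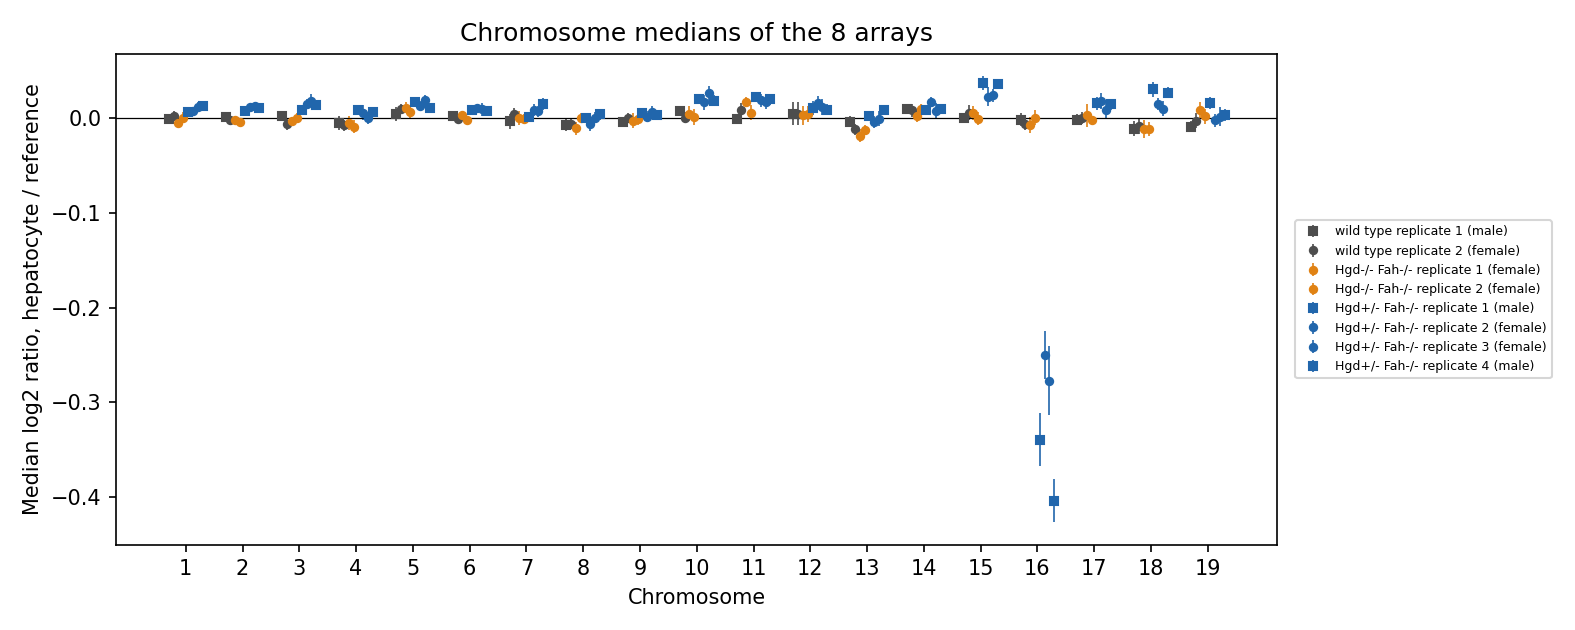
Median log2 ratio of hepatocyte over reference DNA (vertical axis) for each of the 19 autosomes (horizontal axis) in the 8 arrays, with bars for the jackknife standard error within an array, colours for the groups, circles for female and squares for male samples. Chromosome 16 lies between -0.40 and -0.25 in the 4 Hgd+/- Fah-/- samples, and every other median lies between -0.018 and 0.037.

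The remaining 18 autosomes stayed close to 0 in all samples. Their medians lay between -0.018 and 0.037 over the 8 arrays, and none passed the call threshold of 0.1 in absolute value. Chromosome calls therefore numbered 4 in the Hgd+/- Fah-/- group, 0 in the Hgd-/- Fah-/- group and 0 in wild type. When arrays were instead centred on the peak of their log ratios, which moved each by -0.20 to -0.093, the calls numbered 56, 38 and 38, while the chromosome 16 difference was -0.31. Differences between the Hgd+/- Fah-/- samples and the other 4 arrays ran from 0.0033 to 0.031 for these 18 autosomes, with a median of 0.011. Of these, 12 had an exact p of 0.0286 and an adjusted p of 0.0418 over the 19 autosomes, all of them with the Hgd+/- Fah-/- mean higher. The centring used all autosomal probes, chromosome 16 included. A lower chromosome 16 therefore raises the other autosomes, by an amount not computed here. Each array was then recentred on the median of its 18 other autosomes, a step chosen after seeing the data. Chromosomes 15 and 18 differed by 0.017 and 0.021 and chromosome 16 by -0.32, each with an exact p of 0.0286. No other autosome reached that p, and 0 of the 19 had an adjusted p under 0.05. The adjusted p of chromosomes 15, 16 and 18 was 0.181 in these permutation tests. There the smallest exact p of 0.0286 allows an adjusted p under 0.05 only if many autosomes reach it.

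The reduction of chromosome 16 was uneven along its length. The mean profile of the Hgd+/- Fah-/- samples minus the other arrays divided into 5 regions (build mm9). From 3257712 to 24561982 the difference was -0.12, and 8.02% ± 6.34 (SD, n = 4) of the copies were missing, with a range of 1.67% to 15.9%. The samples were uneven here, with 10.2% and 15.9% in the male replicates 1 and 4, and 4.32% and 1.67% in the female replicates 2 and 3. From 24568462 to 33524445 the difference was -0.16 and from 33530498 to 35978161 it was -0.28, with 11.1% and 18.8% of the copies missing. The deepest region ran from 35989011 to 83147197, with a difference of -0.42 and 26.9% ± 3.30 (SD, n = 4) of the copies missing, between 22.8% and 30.8% per sample. From 83165959 to 98280304 the difference was -0.38, and 24.3% were missing. The exact permutation p was 0.0286 for each region. The deepest minus the first region was -0.28, -0.28, -0.38 and -0.25 in Hgd+/- Fah-/- replicates 1 to 4, against 0.0085 to 0.018 in the other arrays (exact p = 0.0286). The regions were found on the arrays they were compared on, and with each Hgd+/- Fah-/- array left out of finding them, its own difference was -0.28, -0.28, -0.38 and -0.25.

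**Figure D2:**
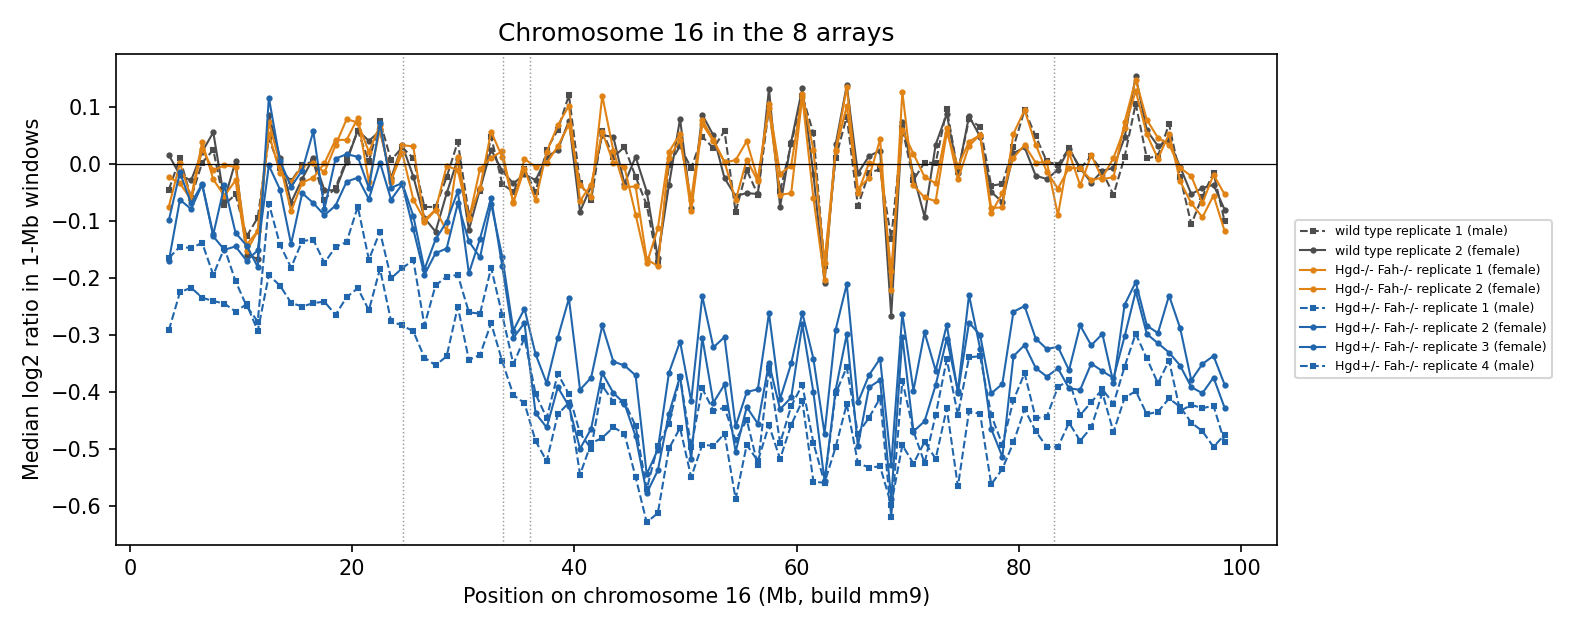
Median log2 ratio in 1-Mb windows (vertical axis) against position on chromosome 16 in Mb, build mm9 (horizontal axis), with a line per array, colours for the groups and dotted lines at the borders of the 5 regions. The 4 Hgd+/- Fah-/- lines fall in steps to the region from 35989011 to 83147197, where their region medians lie between -0.49 and -0.35 and those of the other 4 arrays between -0.0047 and 0.011, although single windows of those arrays dip as well.

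Among the genes of tyrosine breakdown named here, Hgd alone lies on chromosome 16 in the GRCm38.p6 gene table. Tat lies on chromosome 8, Hpd on 5, Gstz1 on 12 and Fah on 7, and the median log2 ratios of these chromosomes had Hgd+/- Fah-/- means of -0.000080, 0.015, 0.012 and 0.0083. The chromosome 16 landmark genes reported here lie on it in the order Crebbp, Socs1, Ahsg, Adipoq, Bcl6, Hes1, Tfrc, Hgd, Gsk3b, Robo1, App, Sod1, Runx1, Dyrk1a, Erg and Ets2. These include the transferrin receptor Tfrc, the secreted liver protein Ahsg and superoxide dismutase Sod1. Which region each falls in was not analysed here, since the gene table and the probes are of different builds. None of the 25 liver growth and tumour genes (0 of 25), such as Met on chromosome 6, Myc on 15, Trp53 on 11 and Ctnnb1 on 9, lies on chromosome 16. Myc shares chromosome 15, whose mean was 0.030 ± 0.0075 (SD, n = 4) in the Hgd+/- Fah-/- samples and 0.0030 ± 0.0037 (SD, n = 4) in the others. With each array recentred on its autosomes other than 16, the chromosome 15 difference was 0.017 (exact permutation p = 0.0286, adjusted p = 0.181).

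Segmentation of each array called 42 altered segments, 18 higher and 24 lower than the reference. Altered autosomal length was 97.7, 68.0, 69.0 and 98.02 Mb in Hgd+/- Fah-/- replicates 1 to 4, against 1.53 Mb in each wild type sample and 17.2 and 2.90 Mb in the Hgd-/- Fah-/- samples. The mean difference of 77.4 Mb had an exact permutation p of 0.0286. Outside chromosome 16 the altered length differed by -2.45 Mb (exact p = 0.971), a comparison added after seeing the data. Its sign rested on Hgd-/- Fah-/- replicate 1, with 17.2 Mb, and without that array the difference was 1.36 Mb (exact p = 0.114), with means of 3.35 and 1.99 Mb. On chromosome 16, replicates 2 and 3 were called from 33622225 to the last probe at 98280304, with means of -0.40 and -0.46. Replicate 1 was called from 3257712 to 33975026 at -0.22 and from 33982171 on at -0.46. In the first of these stretches replicates 2 and 3 were at -0.16 and -0.12, short of the call threshold of 0.2. The other 4 arrays lay between -0.078 and -0.049 there. The lengths thus depend on the threshold, and the mean difference was 94.8 Mb at 0.1 and 68.3 Mb at 0.3. Replicate 4 was called in 3 steps, to 23617154 at -0.28, to 35598510 at -0.37 and from 35607153 on at -0.52. Centring on the peak of the log ratios turned the difference in altered length to -928 Mb (exact p = 0.314). It moved whole arrays by -0.20 to -0.093, so that much length outside chromosome 16 was called. The mean lengths were then 1253 Mb in the Hgd+/- Fah-/- and 2181 Mb in the other arrays.

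Several segments away from chromosome 16 set single samples apart. Hgd+/- Fah-/- replicate 2 had a higher segment on chromosome 2 from 40243358 to 40782074, with a mean of 0.53 over 43 probes against -0.18 to 0.024 in the other 7 arrays. Hgd+/- Fah-/- replicate 3 had a lower segment on chromosome 4 from 111742887 to 113440225, with a mean of -0.67 over 116 probes against -0.050 to -0.00068 in the others. The same sample was lower on chromosome 7 from 26743426 to 26981899, at -2.87 over 10 probes against -0.76 to -0.11. Hgd-/- Fah-/- replicate 1 was called on chromosome 8 from 30658504 to 45250886 at -0.24, where the others lay between -0.18 and -0.076 and 14.8% of the 838 probes were lower than in the others by over 0.3. Shared segments were found on chromosome 14 from 69876584 to 70090608, which was lower in all 6 Fah-/- samples (mean -1.15 ± 0.092, SD, n = 6) and at -0.12 and -0.10 in wild type. A further shared segment on chromosome 7, from 111374510 to 111513989, had a mean of -1.42 ± 0.41 (SD, n = 6) in the Fah-/- samples, 4 of which were called, against -0.23 and -0.24 in wild type. All 8 arrays were higher on chromosome 12 from 114670169 to 116198445, with means between 0.50 and 0.63. On chromosome 14 from 54291227 to 54797503 the means were between 0.30 and 0.39 in all 8 arrays, and 2 of the arrays were called.

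Bins of 1 Mb located the difference between the Hgd+/- Fah-/- samples and the other 4 arrays. Of 2383 autosomal bins, 91 differed at an adjusted p under 0.05 with limma, 7 higher and 84 lower. On chromosome 16, 76 of 96 bins were lower, by a median log2 difference of -0.41, and these included all 74 bins starting after position 25000000. The 20 bins of chromosome 16 that did not pass lay between 3000001 and 25000000. Outside chromosome 16, 15 bins passed. The 3 largest in size were on chromosome 6, where 4 bins passed, and those starting at 50000001, 55000001, 56000001 and 57000001 differed by -0.15 ± 0.014, -0.16 ± 0.018, -0.15 ± 0.014 and -0.12 ± 0.017 (SE), with limma adjusted p of 2.01e-05, 9.50e-05, 2.47e-05 and 8.01e-04. In the same comparison the medians over the probes of these bins were -0.050, -0.024, -0.050 and -0.013, and 8.96%, 14.8%, 19.7% and 17.7% of the probes were lower by over 0.3. With normexp on the raw median signals in place of the processed signals the count was 725, with 636 higher and 89 lower. With chromosome 16 left out of the bins and of the centring, a choice made after seeing the data, 9 bins passed, 2 higher and 7 lower.

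Against wild type alone, the Hgd+/- Fah-/- samples differed in 118 of 2383 bins, 14 higher and 104 lower, and 70 of the lower bins lay on chromosome 16. Against the Hgd-/- Fah-/- samples they differed in 84 bins, 5 higher and 79 lower, with 71 of the lower bins on chromosome 16. Both counts come from 1 limma fit of all 8 arrays. Normexp on the raw median signals gave 364 bins against wild type (273 higher, 91 lower) and 128 against Hgd-/- Fah-/- (55 higher, 73 lower). Centring on all probes gave 0 higher and 102 lower bins against wild type, and centring on the peak of the log ratios gave 0 higher and 84 lower.

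The Hgd-/- Fah-/- samples, which have no functional Hgd copy to lose, differed from wild type in 15 bins, 2 higher and 13 lower. Chromosome 7, which carries Fah, held 5 of them, chromosomes 2 and 13 held 3 each, chromosome 11 held 2 and chromosomes 16 and 17 held 1 each. Among these 15 bins, the largest differences were on chromosome 2 from 51000001 to 52000000 (-0.23 ± 0.022, SE, limma adjusted p = 0.00107) and chromosome 7 from 92000001 to 93000000 (-0.23 ± 0.026, SE, limma adjusted p = 0.00373). In these bins the Hgd+/- Fah-/- means of -0.26 and -0.13 lay near the Hgd-/- Fah-/- means of -0.28 and -0.14, and the wild type means were -0.051 and 0.089. The chromosome 16 bin, from 46000001 to 47000000, had means of -0.092 in wild type, -0.30 in Hgd-/- Fah-/- and -0.63 in Hgd+/- Fah-/- samples. Within the slide that held both groups, fitted alone, 64 bins differed, 9 higher and 55 lower. With the median of the probes of a bin in place of the mean, 0 bins passed.

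Female and male samples, which also differed in the reference used, were compared as a technical control, without a term for group or slide. With limma, 0 of 2383 autosomal bins passed at an adjusted p under 0.05, 245 passed at an unadjusted p under 0.05, and limma-trend with robust variances gave 0. Without wild type replicate 1 the count was 382, with 31 higher and 351 lower in females, and both remaining male samples were then Hgd+/- Fah-/- on 1 slide, so sex, group and slide are mixed in it. Centring on all probes, X and Y included, gave 2076 bins, 1 higher and 2075 lower.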

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

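All tests of explanations in this part were chosen after the results were seen. Of 53 groups of 4 or 5 values, 4 held a sample far from the others by Dixon's ratio. Chance marks about 1 group in 20, a rate that does not hold for segments called on the same values. Hgd+/- Fah-/- replicate 2 had the highest chromosome 14 median of its group, 0.017 against 0.0081 to 0.0096. The jackknife standard errors within these arrays were 0.0055 for replicate 2 and 0.0039 to 0.0086 for the others, so the gap is near the error within an array. Hgd-/- Fah-/- replicate 2 had the lowest Y median of the 5 female samples, -4.35 against -3.99 to -3.87. Hgd+/- Fah-/- replicate 3 stood apart in 2 called segments. It was at -0.63 on chromosome 7 from 111374510 to 111513989, where the other 3 of its group lay between -1.59 and -1.45. It was at -0.67 on chromosome 4 from 111742887 to 113440225, where the others of its group lay between -0.050 and -0.017. The chromosome 4 segment was called in replicate 3 alone, so its mark was built in.

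Chromosome 16 was lower in the 4 Hgd+/- Fah-/- samples, unevenly along its length. A slide effect over the genome is argued against by the largest difference of another autosome, 0.031. For probe variants carried with the Hgd mutation, Hgd-/- Fah-/- minus wild type, on 1 slide, was -0.0032 in the deepest region. This argues against them for the shift of the whole region only, since scattered variants hardly move a median of 2688 probes. Within that region the 1-Mb bin from 46000001 to 47000000 was lower in Hgd-/- Fah-/- than in wild type, by -0.21 (limma adjusted p = 0.0421). Loss of whole copies alone is argued against by the deepest minus first region, -0.31 relative to the other arrays. A candidate explanation is selection for cells that lost the functional Hgd copy, through whole-chromosome loss in some cells and loss of part of the chromosome in others, but DNA of many cells was pooled and the place of Hgd among the regions was not analysed here. In the first region 4.32% and 1.67% of the copies were missing in replicates 2 and 3, which leaves little room for whole-chromosome loss in those samples. An effect of the slide on chromosome 16 alone cannot be told apart from the group.

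The mean of the 6 Fah-/- samples differed from wild type in 35 regions outside chromosome 16, 26 lower and 9 higher, which together spanned 15.1 Mb. Of these, 8 were neighbouring pieces of 1 stretch of chromosome 12, so the regions are not all separate loci. In 30 of the 35 regions both Fah-/- groups differed from wild type by at least 0.1 in the same direction. This is partly built in because the regions were found on these arrays against the same wild type samples. In 17 of the 35 under 50% of the probes were past 0.3. In the chromosome 14 region from 69876584 to 70090608, 100% of the 23 probes were lower by over 0.3, which argues against scattered probe variants, and Hgd-/- Fah-/- minus wild type within 1 slide was -1.001, which argues against a slide effect. In the longest chromosome 7 region, from 91929793 to 93936602, 14.5% of 152 probes were lower by over 0.3 while the median difference was -0.039, so probe variants between strains may account for it, and its difference within the slide was -0.16. An inherited copy difference between the mouse stocks stays open for chromosome 14, and strain was not given in the labels used here.

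Of the 35 splits of the 8 arrays into 4 and 4, only the Hgd+/- Fah-/- split itself gave as many as 91 bins. The highest other gave 1. A share of 1 in 35 is the smallest that these splits allow, so chance is argued against but not excluded. Of the 91 bins, 76 lie on chromosome 16 and are not independent, and this split is also the split by slide. For female against male the real count was 0, so all 56 of the 56 splits into 5 and 3 had to reach it, and the count of splits says nothing there. The highest other split gave 7.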

How the results depend on the processing

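The settings that left out chromosome 16, alone or with an array, used slide 1 alone or recentred on the other autosomes were chosen after seeing the data. Of 182 alternative values, 118 kept their direction and call or stayed within 1.5 times the reported count, 35 moved further, 27 kept their direction without passing the threshold and 2 reversed. These counts do not measure robustness. The value table of the series holds the same numbers as the files, so its values had to stay. The 27 all came from settings with fewer arrays, where no exact permutation p under 0.05 is possible. The chromosome 16 difference ran from -0.43 (normexp) to -0.30 over processing settings, each at an exact p of 0.0286, and was -0.26 and -0.37 within female and male samples. With each array left out it ran from -0.34 to -0.29 (exact p = 0.0571), the X difference from 1.87 to 1.87 and altered length from 72.4 to 82.4 Mb, where fewer arrays leave fewer arrangements. Altered length reversed to -928 Mb with centring on the mode, and to -2.45 Mb outside chromosome 16, where it was 1.36 Mb once Hgd-/- Fah-/- replicate 1 was left out too. Mode centring gave 56, 38 and 38 chromosome calls in Hgd+/- Fah-/-, Hgd-/- Fah-/- and wild type. It moved each array as a whole by -0.20 to -0.093, against call thresholds of 0.1 for chromosomes and 0.2 for segments. These calls and lengths therefore carry a shift of the baseline. The chromosome 16 difference was -0.31 under mode centring and did not reverse. Where no cause is named, the cause was not tested.

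Reported bin counts were 118 for Hgd+/- Fah-/- minus wild type, 84 minus Hgd-/- Fah-/-, 91 minus the other arrays, 15 for Hgd-/- Fah-/- minus wild type and 0 for female minus male. In the first 3, normexp on raw median signals gave 364, 128 and 725, bins of 500 kb gave 241, 156 and 191, bins of 2 Mb gave 63, 39 and 46, and leaving out chromosome 16 gave 42, 9 and 9. Limma-trend with robust variances gave 212 for the first. Hgd-/- Fah-/- minus wild type gave 30 when centred on all probes, 8 on the mode, 31 with bins of 500 kb, 2 with bins of 2 Mb, 0 with the median of probes, 9 with sex as a block and 64 on slide 1 alone. Female minus male gave 2076 when centred on all probes, by the sex difference of X and Y, and 1 with bins of 500 kb. With each array left out the first 3 ran from 84 to 172, 76 to 117 and 82 to 131. Hgd-/- Fah-/- minus wild type ran from 3 to 28, with 3 and 4 without wild type replicates 1 and 2, 6 and 8 without Hgd-/- Fah-/- replicates 1 and 2, and 9 and 28 without Hgd+/- Fah-/- replicates 1 and 3. Where that leaves a group with 1 array, it is assumed to vary like the others. Female minus male ran from 0 to 382, the latter without wild type replicate 1, when both males are Hgd+/- Fah-/-.

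The replicate number as a block gave 207, 150, 112 and 65 bins in the first 4 contrasts. Samples with the same number did not deviate together (r from -0.18 to 0.050), so the numbers are not read as a pairing. Not run were the Hgd region, the gene contrasts and GC content, for want of an mm9 annotation here, the slide as a block with Hgd+/- Fah-/- in the fit, and the sex or replicate block for female minus male. The lowest share of spots well above background in any channel was 99.9%.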

Other observations

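The tests in this part were chosen after the results were seen. Of the loci known to differ in copy between mouse strains, 0 of the 21 matched genes lie on chromosome 16, and the list includes Entpd4 on chromosome 14, Klra8 on chromosome 6, Skint3 on chromosome 4 and Glo1 on chromosome 17. Called segments or bins lay on each of these chromosomes, but also on most other autosomes, so a shared chromosome says nothing about a link. Other members of the list lie on chromosomes without any call. Whether any called segment or bin covers these genes was not analysed here. Of the 35 regions where the mean of the Fah-/- samples differed from wild type, 8 lay on chromosome 12 and 7 on chromosome 7, the chromosome of Fah. The 8 on chromosome 12 were neighbouring pieces of 1 stretch, from 114849355 to 117285162, in both directions, so they are not separate loci. That stretch overlaps the segment that was higher in all 8 arrays. The 7 on chromosome 7 include the region from 26790284 to 27012016. It had a Hgd-/- Fah-/- minus wild type difference of 0.019 and overlaps the segment at -2.87 in Hgd+/- Fah-/- replicate 3. On chromosome 17, the region from 22675168 to 22785051 was higher in all 6 Fah-/- samples, at 0.83 ± 0.22 (SD, n = 6) against 0.081 and 0.11 in wild type, and 100% of its 11 probes differed by over 0.3. The segment on chromosome 12 from 116207489 to 116624944 was at -1.32 and -1.52 in Hgd+/- Fah-/- replicates 3 and 4 and between -0.095 and 0.15 in the other 6 arrays.

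Bins of 500 kb that exceeded 0.2 in all 8 arrays numbered 3, with 2 on chromosome 12 and 1 on chromosome 14. Antigen receptor genes lie on chromosomes 6, 12, 13, 14 and 16 in the GRCm38.p6 gene table, and they are rearranged with loss of DNA in the lymphocytes that make up much of a splenocyte reference. That loss is a candidate explanation for these bins. Counted per locus, the chance that both loci fall on such chromosomes was 0.0605, the smallest that 2 loci allow, so this test could not pass 0.05 and leaves the question open. Counted per bin, Fisher's exact test gave a one-sided p of 0.0149, but this was computed first and set aside because 2 of the bins are of 1 locus. Chromosome 16 holds receptor genes too, but loss of DNA from the reference would raise the ratio, whereas chromosome 16 was lower. The reference was wild type splenocyte DNA on all 8 arrays, and the 4 other arrays showed no chromosome-wide shift, with a mean of -0.0034. That is a mean of whole-chromosome medians, which cannot show a shift at a single locus.

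Male Hgd+/- Fah-/- samples had lower chromosome 16 medians than female ones by a difference of -0.11, with an exact permutation p of 0.333, the smallest that 2 against 2 samples allow.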
